A study of Ovis aries with 8 samples.

How the data were processed

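Pancreatic islets of 8 fetal sheep, 4 growth-restricted (IUGR) and 4 control, were compared by mRNA sequencing. The groups, sexes, gestational ages and fetal weights were taken from the labels of each sample. IUGR was produced by keeping pregnant ewes in the heat, and the ewes of the control fetuses were pair-fed, per the labels' protocols. Islets were picked by hand and frozen before RNA extraction, and libraries were made with a TruSeq kit and read in 100 bp pairs, per the labels' protocols.

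The authors deposited one table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with 1 column per library and 25000 rows, and whether it is complete is unknown. TopHat2 2.0.1, Cufflinks 2.1.1 and Cuffdiff and the sheep build Oar_v3.1 are named in the submitters' processing notes, which give no order or settings. FPKM is already divided by transcript length and by library size, so it holds no counts. Low values showed no whole-read steps, so the depth of each library is unknown and no counting interval or detection floor was given. The sum of FPKM per library ran from 832471 in IUGR 1 to 4498805 in IUGR 4, because a few rows, several of them very short, reached up to 1510340 FPKM in some libraries and were listed at or near 0 in others. Between 16409 and 16937 rows per library were above 0. A value of 0 can be a failed estimate, so such genes are described only as listed at 0.

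Gene symbols came from the table. Of its rows, 18204 carried a symbol and 6796 did not, and 6430 rows were at 0 in every library. Coordinates are those of the table on Oar_v3.1. A reference genome of that build was not used here, so exons, introns and untranslated regions were not assigned. The RefSeq gene table at hand belongs to the assembly ARS-UI_Ramb_v3.0, and it was used only for synonyms, which placed 10 list genes. A locus in the table can join neighbouring genes. Insulin and pancreatic polypeptide had no row under the symbols INS and PPY and were not analysed here, although they may lie among the rows without a symbol.

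The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(FPKM + 1), over the 13557 rows with a mean FPKM of at least 1 across the 8 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are on the scale of FPKM plus a pseudocount of 1, which understates the change of low genes. Means are given with SD and log2 fold changes with SE. Folds of means are ratios of mean FPKM. Each library carried its own fetal weight, sex and gestational age, and the pregnancies were singleton, per the labels, but p-values measure only the spread between these 8 samples.

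Before the data were examined, 21 pathway lists and 9 lists of cell type markers were written down, together holding 738 distinct genes. A row was found for 630 of them and 579 were tested. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists. Each list was also tested with camera at an estimated correlation and with fry. The number of members that passed is given adjusted over all genes and adjusted over the list alone. A list score is the mean log2(FPKM + 1) of the tested members. Fetal weight, gestational age, marker scores and the hormone share of FPKM were compared by exact permutation tests, two-sided, over 70 arrangements, for which the smallest possible p is 0.0286.

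The genes named in the text were chosen by a rule fixed before the data were examined. Among genes with a symbol and without overlap between groups, it took the 12 largest changes per direction past the threshold. Where fewer than 5 passed, it added those of smallest p up to 5. From each list it took up to 5 members with an adjusted p under 0.05, or else the 2 members of smallest p. It always took the hormones, PDX1, MAFA, SLC2A2, GCK, ADRA2A, UCP2 and MKI67. Other members are named as examples of those that passed over their list alone, and were chosen after their values were seen.

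Alternatives covered the pseudocount (0.1), the filter (none, or a mean FPKM of at least 5), 4 scalings between libraries, a robust variance without the trend, library quality weights, sex, gestational age and marker scores as covariates, the replicate number as a block, and leaving out each library. The steps were tested on simulated data with the real means and spreads of the 13557 genes for the comparison of IUGR with control. Of 50 genes changed by each amount, 15 were recovered at a log2 change of 1, 41 at 2, 45 at 3 and 48 at 4, and 9 of 158 called genes had not been changed. These changed genes were drawn only from genes outside the lists with a mean log2(FPKM + 1) above 3, so recovery of lower genes was not measured. The simulated genes varied independently of one another, unlike genes in tissue. Figures were drawn with matplotlib 3.10.9.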

Results

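Islets of Langerhans, the clusters of hormone-secreting cells in the pancreas, were collected from near-term fetuses of Columbia-Rambouillet crossbred sheep. The comparison asked which islet transcripts differ when placental insufficiency has restricted fetal growth. The labels give the heat for all IUGR pregnancies and for no control, so it cannot be told apart from growth restriction. By the labels the heat ended before the gestational ages given below. The 4 IUGR fetuses (3 female, 1 male) weighed 1.25 ± 0.058 kg (SD, n = 4) and the 4 controls (1 female, 3 male) weighed 3.5 ± 0.42 kg (SD, n = 4). The exact permutation p for weight was 0.0286, the smallest this design allows. Gestational age was 135.2 ± 3.1 days in IUGR and 133.8 ± 3.3 days in controls (SD, n = 4 each, exact permutation p = 0.543). Expression was given as FPKM, and the sequencing depth behind it is unknown.

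The IUGR libraries resembled one another more closely than the controls did. Pearson correlations across genes of log2(FPKM + 1) were 0.899 to 0.944 within IUGR, 0.824 to 0.926 within controls and 0.807 to 0.931 between groups. The first principal component held 39.0% of the variance, and Control 1 (-93.3) and Control 4 (-75.1) lay far from the other 6 libraries, which ran from 5.33 to 38.9. Members of the interferon response, duct and antioxidant lists had median correlations with this component across libraries of -0.83, -0.84 and -0.80, and endothelial markers 0.85. These correlations span both groups. Among controls, the interferon, antioxidant and endothelial list scores set Control 1 and Control 4 apart from Control 2 and Control 3. The duct score was 7.57 in Control 1, while Control 4 (5.81) lay near Control 2 (5.60) and Control 3 (5.18).

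**Figure D1:**
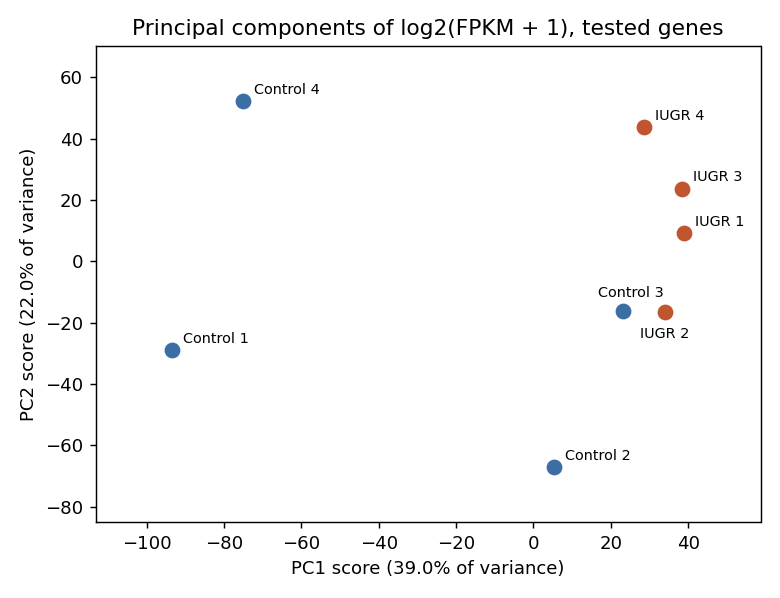
Scores of the 8 libraries on the first principal component (horizontal axis) and the second (vertical axis) of log2(FPKM + 1), with controls in blue and IUGR in orange. Control 1 and Control 4 lie at -93.3 and -75.1 on the first component, and the IUGR libraries lie between 28.7 and 38.9.

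WFDC10A, GABPB2 and CRB1 rose in IUGR islets and no gene fell at the adjusted threshold (limma, adjusted p = 0.0407 for each of the 3). GABPB2, a subunit of the GA-binding transcription factor (chromosome 1, 99914212 to 99930907), went from 4.06 ± 2.0 to 56.6 ± 25 FPKM (SD, n = 4), a 13.9-fold difference of means and a log2 change of 3.49 ± 0.39 (SE). CRB1, a cell polarity protein (chromosome 12, 74372413 to 74515404), went from 0.327 ± 0.32 to 7.86 ± 2.6 FPKM (SD, n = 4). WFDC10A (chromosome 13, 73998073 to 73998217) was listed at 0 in all 4 controls and at 47.3, 541.8, 66.0 and 51.5 FPKM in IUGR 1 to 4, in a locus spanning only 144 bp. The genes of next smallest p were taken among those with a symbol and without overlap between groups. On the higher side, DAPL1 was at 1.24 ± 1.2 and 14.2 ± 3.9 FPKM in control and IUGR (limma, adjusted p = 0.0678). The collagen COL6A3 was at 38.4 ± 5.5 and 112.8 ± 20 FPKM (limma, adjusted p = 0.0678). On the lower side, IFI6, an interferon-induced gene, was at 673.1 ± 95 FPKM in controls and 64.7 ± 56 in IUGR (adjusted p = 0.0678). INHBE, an inhibin subunit, was at 13.5 ± 10 and 0.224 ± 0.20 (adjusted p = 0.0698). The lysosomal protease CTSL was at 13.1 ± 7.2 and 0.888 ± 0.12, TGFBI at 95.9 ± 37 and 25.1 ± 8.1, and the mucin MUC1 at 35.1 ± 34 and 2.86 ± 0.81 FPKM, with adjusted p of 0.129, 0.173 and 0.173.

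At an unadjusted p under 0.05 there were 2315 genes, 17.1% of those tested, with 1054 higher and 1261 lower in IUGR. That count was 1243 without Control 1, 1476 without IUGR 1, 1501 without IUGR 3, 1520 without IUGR 4, 3458 without Control 3, 627 rescaled to the same sum and 236 with the duct score. Rescaled without the 20 highest genes, which moved the median of all genes by 0.213, it was 1893 higher and 530 lower. The values of the groups did not overlap for 1208 genes, or 8.91%, where chance gives 2.86% on average over arrangements of the libraries. Genes vary together, so a single arrangement can lie far from that average. Overlap was not counted in other arrangements. The count of 3 was 0 without Control 1, without Control 4, without both, without IUGR 1 or without IUGR 3, and 12 without IUGR 4 (5 higher, 7 lower). Without Control 2 it was 1 higher and 2 lower, with none of the 3 genes among them, and without Control 3 it was 2 higher and 1 lower, with 1 of the 3. Without IUGR 2 it was 2 higher, with WFDC10A alone of the 3. GABPB2 and CRB1 were then at log2 changes of 3.63 and 2.63 (limma, adjusted p = 0.105 and 0.198). A pseudocount of 0.1 left 1 gene, WFDC10A, with GABPB2 and CRB1 at adjusted p of 0.0562 and 0.0687 (limma). The count was also 0 with library quality weights, without a filter on low values, and with gestational age, the duct score or the mesenchymal score as a covariate, 100 with every library rescaled to the same sum (31 higher, 69 lower), and 116 with the acinar score as a covariate (41 higher, 75 lower). With the replicate number as a block the count was 11 (4 higher, 7 lower), the 3 genes among them. The log2 changes of WFDC10A, GABPB2 and CRB1, 6.62, 3.49 and 2.71 with and without the filter on low values, were 6.47, 3.43 and 2.65 with quality weights and 6.52, 3.64 and 2.70 with gestational age. They were 5.28, 3.34 and 2.29 with the mesenchymal score, and 7.63, 2.48 and 2.81 with the duct score. With sex as a covariate 2 genes passed, of which 1 was among the 3, and the calls of WFDC10A and CRB1 ended (adjusted p = 0.118 and 0.0976) while their log2 changes stayed about as large, at 6.43 against 6.62 and 2.91 against 2.71.

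**Figure D2:**
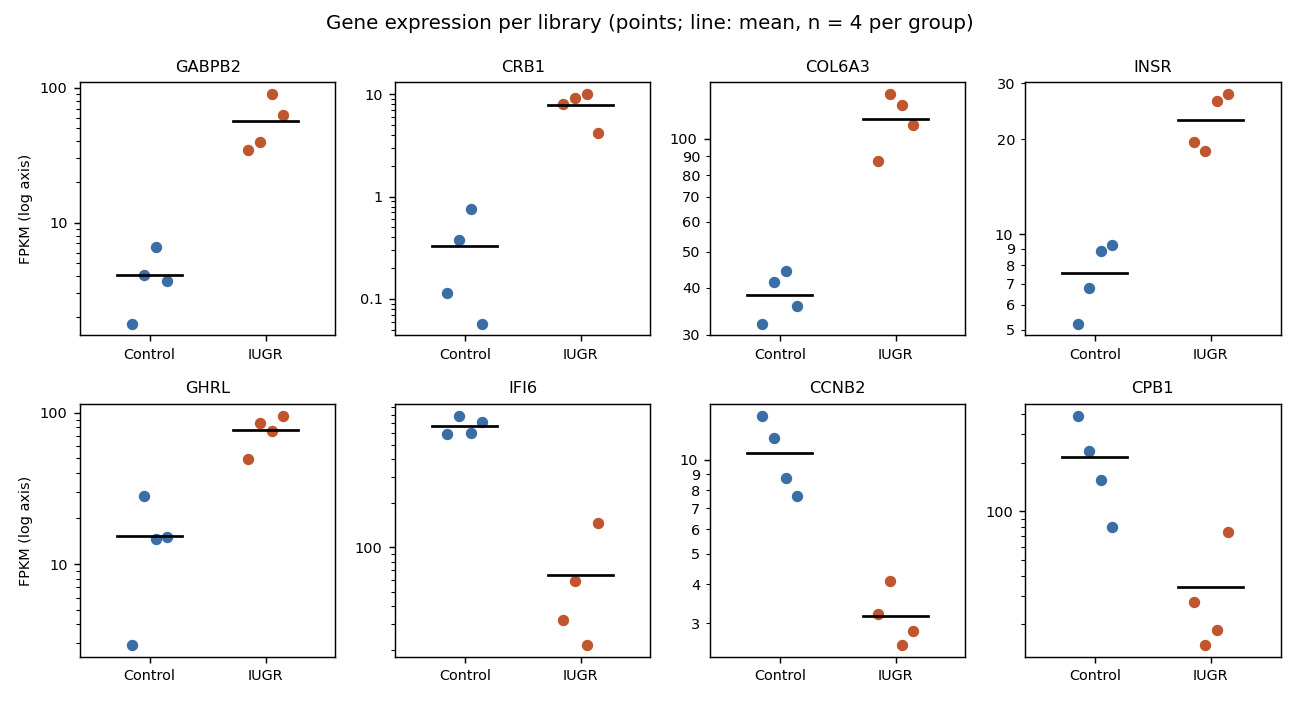
FPKM on log axes for 8 genes in the 4 control (blue) and 4 IUGR (orange) libraries, each point a library and each line a group mean. GABPB2 averages 4.06 in controls and 56.6 in IUGR, and IFI6 averages 673.1 and 64.7.

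Of the 30 lists, 10 were higher and 11 lower in IUGR relative to the other genes (camera, adjusted over the lists). With an estimated correlation between genes none passed, and the lowest adjusted p was 0.316. The fry test found 1 list moving on balance one way, cell cycle and proliferation (adjusted p = 0.0201), and 8 lists with changes in either direction. No list member passed in adjustment over all genes, so the members counted below as rising or falling passed when adjusted over the list alone. Where a list call ended in a refit, brackets hold the mean log2 fold change of that refit and its adjusted p. Several calls ended while the mean stayed as large or grew. The duct and mesenchymal scores themselves separated the groups without overlap. A call that ended with either score in the fit therefore cannot tell that score apart from growth restriction.

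**Figure D3:**
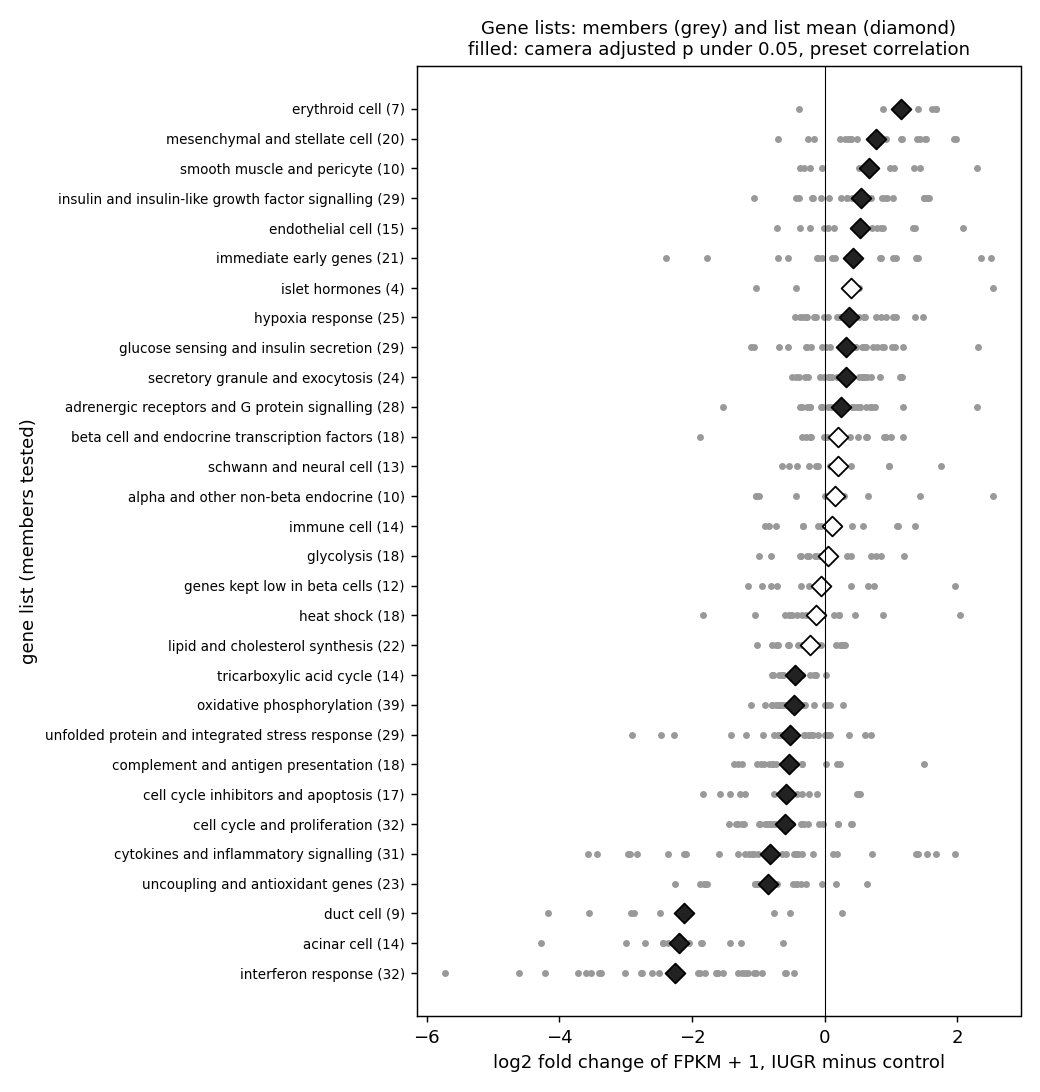
Log2 fold change, IUGR minus control (horizontal axis), of the tested members (grey points) and the mean (diamonds) of each of 30 gene lists (vertical axis), with filled diamonds for lists past the camera threshold at the preset correlation. The interferon list has the lowest mean, -2.25, and the erythroid list the highest, 1.15.

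Interferon response genes, which cells switch on during viral infection, were lower in IUGR for all 32 tested members, with a median log2 fold change of -1.90. In adjustment over the list alone 25 fell and 7 did not pass. The groups were without overlap for only 7 of the 32 members. The estimated correlation between members was 0.74, so the 25 are not separate changes. IFI6 was 10.4-fold lower, the antiviral GTPase MX1 went from 343.0 ± 286 to 18.6 ± 24 FPKM, and OAS2, which senses double-stranded RNA, from 63.8 ± 31 to 7.61 ± 11 (SD, n = 4). The ubiquitin-like gene ISG15, listed as ISG17, went from 1533 ± 1544 to 31.5 ± 46 FPKM. The list's adjusted p was 1.27e-17, and 0.316 with an estimated correlation. The list score was 6.13 and 6.40 in Control 1 and Control 4, 5.15 and 4.28 in Control 2 and Control 3, 2.70 to 2.80 in IUGR 1 to 3 and 4.66 in IUGR 4. Without Control 1 and Control 4 together, 1 member fell.

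Cell cycle genes were lower for 28 of 32 tested members, with a median log2 fold change of -0.64, and all 4 IUGR scores (2.86 to 2.98) lay below the control scores (3.26 to 3.68). In adjustment over the list alone 12 fell and 20 did not pass. The mitotic cyclin CCNB2 went from 10.5 ± 2.8 to 3.17 ± 0.68 FPKM, thymidylate synthase TYMS from 27.2 ± 7.4 to 9.89 ± 1.3, and the replication helicase subunit MCM5 from 30.0 ± 8.0 to 11.3 ± 2.2 (SD, n = 4). MKI67, a marker of dividing cells, was at 5.84 ± 2.2 and 3.14 ± 0.63 FPKM (adjusted p = 0.278 over all genes). The list's adjusted p was 7.01e-09, and 0.316 with an estimated correlation. The count of 12 was 6 without IUGR 3 or IUGR 4, 7 without Control 2 or IUGR 1, and 14 without Control 1 and Control 4 together.

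Genes of insulin and insulin-like growth factor signalling were higher for 23 of 29 tested members, with a median log2 fold change of 0.57. In adjustment over the list alone 4 rose, and each encodes a receptor or ligand of the pathway. The insulin receptor INSR (chromosome 5, 13733595 to 13879145) was 3.05-fold higher, at 7.55 ± 1.9 FPKM in controls and 23.0 ± 4.8 in IUGR (SD, n = 4). The growth factor IGF2 (chromosome 21, 48655289 to 48681619) went from 208.5 ± 89 to 594.5 ± 192 FPKM, its receptor IGF1R from 25.0 ± 15 to 67.9 ± 6.8, and the clearance receptor IGF2R from 44.1 ± 19 to 86.6 ± 14. The list's adjusted p was 5.29e-05, and 0.316 with an estimated correlation. The list mean was 0.543, and the call ended with the duct score as a covariate (0.118, adjusted p = 0.134), the number that rose was 8 without Control 3, and it was 1 without Control 1 and Control 4 together.

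Ghrelin, GHRL, was the islet hormone that rose, from 15.2 ± 10 to 76.8 ± 20 FPKM (SD, n = 4, log2 change 2.54 ± 0.54 SE), in adjustment over the list alone. Glucagon, GCG, was at 1248 ± 603 FPKM in controls and 866.4 ± 286 in IUGR (adjusted p = 0.568 over all genes), and somatostatin, SST, at 503.5 ± 402 and 198.0 ± 36 (adjusted p = 0.307). The amyloid peptide gene IAPP was listed at 0 in all 8 libraries. The 4 hormones tested did not pass as a list (2 higher and 2 lower, adjusted p = 0.693). Hormone genes held 0.140 ± 0.086% of all FPKM in controls and 0.0788 ± 0.039% in IUGR (SD, n = 4, exact permutation p = 0.257), a share that leaves out insulin and rests on its denominator. It was 0.237% and 0.190% without the 20 other highest genes (exact permutation p = 0.457), where IUGR 4 went from the lowest IUGR library (0.0327%) to the highest (0.249%). Without rows of very high FPKM it was 0.170% and 0.137% (exact permutation p = 0.429).

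Endocrine transcription factors did not pass as a list (12 of 18 higher, adjusted p = 0.238). PDX1, a master regulator of beta cells, was at 446.9 ± 131 and 446.3 ± 135 FPKM in control and IUGR, and MAFA, which activates insulin transcription, at 9.32 ± 8.6 and 13.1 ± 13. PAX4 was at 9.15 ± 4.4 and 1.95 ± 1.8 and MYT1 at 14.7 ± 10 and 24.4 ± 4.9. Markers of alpha and other non-beta endocrine cells were higher for 6 of 10 members (adjusted p = 0.892), with GHRL as the 1 that rose, and transthyretin, TTR, was at 565.5 ± 214 and 267.4 ± 73.

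Genes of glucose sensing and insulin secretion were higher for 21 of 29 members (adjusted p = 0.0155, and 0.550 with an estimated correlation). The lipid receptor GPR119 rose 4.49-fold, from 14.8 ± 12 to 66.6 ± 24 FPKM, in adjustment over the list alone, and was not past that threshold without Control 1, 3 or 4 or IUGR 1, 2 or 3. The incretin receptor GLP1R was at 6.43 ± 1.8 in controls and 2.64 ± 1.2 in IUGR, the glucose transporter SLC2A2 at 27.1 ± 12 and 59.6 ± 36, and glucokinase, GCK, at 115.5 ± 57 and 133.2 ± 41 FPKM. The list mean was 0.323, and the call ended without Control 1 (0.137, adjusted p = 0.144) or IUGR 1 (0.193, adjusted p = 0.0913), rescaled to the same sum (0.264, adjusted p = 0.0571), with the mesenchymal score (0.085, adjusted p = 0.459) and without Control 1 and Control 4 together (0.032, adjusted p = 0.332), and with the duct score the mean was -0.17.

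Secretory granule and exocytosis genes were higher for 17 of 24 members (adjusted p = 0.0383, and 0.526 with an estimated correlation). The granule protein CHGA was at 5404 ± 3259 and 10667 ± 3113 FPKM in control and IUGR, and the calcium sensor SYT7 at 57.6 ± 34 and 112.9 ± 25. The list mean was 0.321, and this call ended without Control 1 (0.163, adjusted p = 0.159), Control 2 (0.344, adjusted p = 0.0578) or IUGR 4 (0.280, adjusted p = 0.0849), rescaled to the same sum (0.249, adjusted p = 0.109), with the acinar (0.290, adjusted p = 0.530) or mesenchymal score (0.191, adjusted p = 0.242) and without Control 1 and Control 4 together (0.135, adjusted p = 0.163). With the duct score the granule list passed in the opposite direction, lower in IUGR (mean -0.23, camera, adjusted p = 0.0289). Adrenergic receptor and G protein genes were higher for 19 of 28 members (adjusted p = 0.0315, and 0.316 with an estimated correlation), with a mean of 0.249. Their call ended without Control 1 (0.170, adjusted p = 0.0542), rescaled to the same sum (0.174, adjusted p = 0.176), with the acinar (0.308, adjusted p = 0.0974), mesenchymal (0.139, adjusted p = 0.459) or duct score (-0.037, adjusted p = 0.873) and without Control 1 and Control 4 together (0.106, adjusted p = 0.171). The alpha-2A adrenergic receptor ADRA2A, which restrains insulin secretion, was at 55.6 ± 13 and 83.2 ± 30 FPKM (adjusted p = 0.369 over all genes), ADCY9 at 5.69 ± 1.1 and 9.83 ± 0.66, and RGS16 at 145.4 ± 101 and 41.3 ± 9.0. With Control 3 left out, 3 members of each of these lists rose over the list alone, against 0 with all 8 libraries.

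Genes of mitochondrial energy metabolism were lower in IUGR by modest amounts. Oxidative phosphorylation genes were lower for 35 of 39 members, with a median log2 fold change of -0.45 (adjusted p = 6.95e-07, and 0.526 with an estimated correlation), although no single member passed over the list alone. With Control 3 left out, 1 member of this list fell. The complex I subunit NDUFV1 was at 171.1 ± 48 and 89.3 ± 9.3 FPKM in control and IUGR, and the complex III subunit UQCRC1 at 206.4 ± 45 and 121.6 ± 15 (SD, n = 4). Tricarboxylic acid cycle genes were lower for 13 of 14 members (median -0.50, adjusted p = 0.000333, and 0.361 with an estimated correlation). In adjustment over the list alone MDH2 fell from 340.6 ± 82 to 194.8 ± 18, OGDH from 90.5 ± 28 to 50.2 ± 3.4 and IDH3B from 165.9 ± 23 to 106.5 ± 13 FPKM. That count of 3 was 6 without Control 3 and 0 without any other single library. The list means were -0.460 and -0.451, and both calls ended with the duct score as a covariate (-0.033, adjusted p = 0.748, and -0.076, adjusted p = 0.424). The oxidative phosphorylation call also ended with the acinar score (-0.195, adjusted p = 0.0972), and the tricarboxylic acid cycle call with the mesenchymal score (-0.426, adjusted p = 0.0511) and rescaled to the same sum (-0.517, adjusted p = 0.0716).

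Uncoupling and antioxidant genes were lower for 21 of 23 members (median -0.85, adjusted p = 0.000139, and 0.316 with an estimated correlation). The peroxidase PRDX2 was at 860.9 ± 321 and 395.3 ± 49 FPKM in control and IUGR, GPX7 at 107.0 ± 7.0 and 64.3 ± 14, and the uncoupling protein UCP2 at 130.6 ± 79 and 60.3 ± 23 (adjusted p = 0.296 over all genes). Their list score was 7.05 and 6.97 in Control 1 and Control 4 against 5.41 to 5.92 in the other 6 libraries, and without both the call ended (-0.249 against a mean of -0.858, adjusted p = 0.0654). It also ended with the mesenchymal score (-0.132, adjusted p = 0.473) and the duct score (-0.206, adjusted p = 0.352). With Control 3 left out, 9 members fell over the list alone. Glycolysis genes did not pass (8 of 18 higher, adjusted p = 0.791), with a mean of 0.052 and a median of -0.065 that differ in sign. The lactate transporter SLC16A3 was at 9.85 ± 6.2 and 21.4 ± 3.0 FPKM and PFKP at 38.6 ± 22 and 16.9 ± 4.6. Hypoxia response genes were higher for 17 of 25 members (adjusted p = 0.00436, and 0.372 with an estimated correlation), with a mean of 0.371. The hypoxia call ended without Control 3 (0.275, adjusted p = 0.0710), rescaled to the same sum (0.275, adjusted p = 0.0606) and with the acinar score (0.138, adjusted p = 0.530). The collagen cross-linking enzyme LOX rose from 0.579 ± 0.47 to 3.41 ± 1.1 FPKM in adjustment over the list alone, but not without Control 1 or IUGR 1, 2 or 3, and 5 members rose without Control 4 and 2 without Control 2. The collagen hydroxylase P4HA1 was at 6.37 ± 2.8 and 13.8 ± 2.5, so both named members act on collagen.

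Unfolded protein and integrated stress response genes were lower for 20 of 29 members (adjusted p = 0.00778, and 0.316 with an estimated correlation), with a mean of -0.524. That call ended without Control 4 (-0.456, adjusted p = 0.0647) or both Control 1 and Control 4 (-0.228, adjusted p = 0.125), by quantiles (-0.398, adjusted p = 0.0889), and with the mesenchymal (-0.084, adjusted p = 0.997) or duct score (-0.055, adjusted p = 0.311). The serine synthesis enzyme PHGDH fell from 102.5 ± 113 (271.3 in Control 1, 34.0 to 56.9 in the other 3) to 8.96 ± 3.3 FPKM in adjustment over the list alone, but not without IUGR 1, 3 or 4, and 2 members fell without Control 2. TRIB3 was at 22.4 ± 26 and 2.35 ± 2.3. Lipid and cholesterol synthesis genes did not pass (16 of 22 lower, adjusted p = 0.107), although they did without Control 2 (0.00982), IUGR 1 (0.0162) or IUGR 3 (0.0475). The mevalonate enzymes MVD and MVK were at 61.0 ± 9.8 and 34.8 ± 5.8, and at 20.8 ± 6.9 and 12.0 ± 2.3 FPKM. Genes kept low in beta cells did not pass (8 of 12 lower, adjusted p = 0.573). Of these ACOT7 fell from 29.6 ± 5.5 to 14.9 ± 2.9 in adjustment over the list alone, but not without Control 1, IUGR 3 or IUGR 4 (2 fell without IUGR 1), and the chemokine CXCL12 was at 22.6 ± 20 and 68.7 ± 26.

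Cytokine and inflammatory genes were lower for 23 of 31 members (median -0.73, adjusted p = 0.0155, and 0.650 with an estimated correlation). Nitric oxide synthase NOS2 fell from 6.33 ± 4.5 to 0.472 ± 0.11 FPKM in adjustment over the list alone, but not without Control 1, IUGR 1 or IUGR 3 (5 fell without Control 3, 2 without IUGR 4), and the chemokine CCL8 was at 81.7 ± 80 and 4.47 ± 4.6. The list mean was -0.825, and the call ended without Control 4 (-0.301, adjusted p = 0.404), IUGR 1 (-0.665, adjusted p = 0.0781) or IUGR 2 (-0.719, adjusted p = 0.0725), at a mean FPKM of at least 5 (-0.770, adjusted p = 0.215) and with sex (-0.796, adjusted p = 0.132) or gestational age (-0.546, adjusted p = 0.117), and the mean was 0.47 with the mesenchymal score and 0.044 without Control 1 and Control 4 together. Complement and antigen presentation genes were lower for 14 of 18 members (adjusted p = 0.0308, and 0.650 with an estimated correlation), with a mean of -0.541. That call ended without Control 2 (-0.137, adjusted p = 0.488), Control 3 (-0.460, adjusted p = 0.107), IUGR 1 (-0.396, adjusted p = 0.0879) or IUGR 2 (-0.479, adjusted p = 0.0876), and with sex (-0.391, adjusted p = 0.213) or the acinar score (-0.143, adjusted p = 0.530). SERPING1 was at 245.3 ± 94 and 102.8 ± 37 FPKM and C7 at 28.5 ± 21 and 66.9 ± 15. Cell cycle inhibitor and apoptosis genes were lower for 14 of 17 members (adjusted p = 0.0448, and 0.408 with an estimated correlation), with a mean of -0.589. That call ended without Control 1 (-0.409, adjusted p = 0.149), Control 4 (-0.465, adjusted p = 0.182), IUGR 1 (-0.470, adjusted p = 0.0913), IUGR 2 (-0.650, adjusted p = 0.0505) or IUGR 4 (-0.581, adjusted p = 0.0540). With the duct score the mean turned to 0.084. The call was lost in 14 of 24 refits in all, those with sex (-0.702, adjusted p = 0.0843), gestational age (-0.479, adjusted p = 0.124) and the mesenchymal score (-0.128, adjusted p = 0.997) among them. BAK1 was at 29.3 ± 7.3 and 16.5 ± 2.8, and BAX at 215.8 ± 136 and 68.1 ± 20.

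Immediate early genes were higher for 14 of 21 members (adjusted p = 0.0435, and 0.550 with an estimated correlation). The antiproliferative gene BTG2 rose 2.49-fold, from 115.9 ± 39 to 288.5 ± 25 FPKM, in adjustment over the list alone, but not without IUGR 2 or IUGR 4 (3 rose without Control 3), and FOSB was at 41.4 ± 54 and 136.6 ± 110. The list mean was 0.420, and the call ended without Control 1 (0.285, adjusted p = 0.0542), Control 2 (0.338, adjusted p = 0.290), IUGR 1 (0.411, adjusted p = 0.0513) or IUGR 2 (0.233, adjusted p = 0.272). It also ended rescaled to the same sum (0.368, adjusted p = 0.0571) or without the 20 highest genes (0.640, adjusted p = 0.125), and with the acinar (0.635, adjusted p = 0.0891) or mesenchymal score (0.076, adjusted p = 0.483). Heat shock genes did not pass (12 of 18 lower, adjusted p = 0.325). The chaperone CRYAB was at 110.4 ± 142 and 17.2 ± 5.1 FPKM and HSPA1L at 3.86 ± 3.6 and 6.64 ± 0.91.

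Markers of exocrine cells were lower in IUGR islets, and markers of connective tissue and red blood cells were higher. Acinar markers, the digestive enzymes of the exocrine pancreas, were lower for all 14 tested members (median -2.26, adjusted p = 2.83e-06, and 0.361 with an estimated correlation). In adjustment over the list alone 6 fell, among them the carboxypeptidase CPB1, from 216.5 ± 134 to 33.9 ± 28 FPKM, and the trypsin inhibitor SPINK1, from 95.2 ± 139 to 1.37 ± 0.95, with 302.4 in Control 1 and 10.4 to 51.5 in the other 3 controls. Duct markers were lower for 8 of 9 (median -2.48, adjusted p = 0.000251, and 0.316 with an estimated correlation), and 5 fell, including MUC1 and the tight junction protein CLDN4, at 340.1 ± 559 and 7.07 ± 6.6, where Control 1 was at 1174.9 and the other 3 controls at 24.5 to 127.7 FPKM. The acinar count of 6 was 2 without Control 2, 11 without Control 4 and 14 without Control 1 and Control 4 together. The duct count of 5 was 2 without Control 1, 3 without IUGR 1 and 1 without IUGR 3 or IUGR 4. The duct call ended with the mesenchymal score as a covariate (-1.83 against a mean of -2.12, adjusted p = 0.155).

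Mesenchymal and stellate cell markers were higher for 17 of 20 members (median 0.77, adjusted p = 3.91e-05, and 0.316 with an estimated correlation). COL6A3 rose 2.94-fold, COL5A1 2.81-fold, COL14A1 4.27-fold, FBN1 2.25-fold and DPT 3.46-fold in adjustment over the list alone, and the other 15 did not pass. That count of 5 was 10 without Control 2 and 3 without Control 1, IUGR 1, IUGR 4, or Control 1 and Control 4 together. Erythroid markers were higher for 6 of 7 (median 1.41, adjusted p = 0.00127, and 0.316 with an estimated correlation) and 5 rose, including the red cell anion exchanger SLC4A1, from 0.283 ± 0.34 to 3.28 ± 1.9 FPKM, and AHSP, from 1.79 ± 1.4 to 8.44 ± 6.4. That count was 3 without Control 2, 2 without IUGR 3, and 1 without Control 1, Control 4, IUGR 1 or IUGR 2, and the call ended with the mesenchymal score as a covariate (0.894 against a mean of 1.15, adjusted p = 0.0860).

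Endothelial markers were higher for 11 of 15 members (adjusted p = 0.0350, and 0.550 with an estimated correlation), with a mean of 0.535. The endothelial call ended without Control 1 (0.269, adjusted p = 0.149), Control 4 (0.455, adjusted p = 0.0703) or IUGR 2 (0.479, adjusted p = 0.0948), with quality weights (0.423, adjusted p = 0.0536) or with gestational age (0.458, adjusted p = 0.0919), and without Control 1 and Control 4 together the mean log2 fold change was 0.015. It turned to -0.192 with the mesenchymal score and -0.238 with the duct score. The vascular growth factor receptor FLT1 was at 16.0 ± 12 and 56.6 ± 18 FPKM in control and IUGR, and TEK at 12.4 ± 6.6 and 28.6 ± 5.2. Smooth muscle and pericyte markers were higher for 6 of 10 (adjusted p = 0.0492, and 0.549 with an estimated correlation), with a mean of 0.670. The smooth muscle call ended without Control 3 (0.787, adjusted p = 0.0701), Control 4 (0.336, adjusted p = 0.390), IUGR 2 (0.537, adjusted p = 0.179) or IUGR 3 (0.644, adjusted p = 0.0562), and in 11 of 24 refits in all, those with sex (0.690, adjusted p = 0.147) and gestational age (0.527, adjusted p = 0.117) among them, and the mean turned to -0.266 with the mesenchymal score. RGS5 was at 15.8 ± 20 and 44.5 ± 13 and NOTCH3 at 9.17 ± 6.4 and 23.0 ± 8.3. Over the list alone, 3 endothelial and 4 smooth muscle markers rose with Control 2 left out, against 0 with all 8 libraries. Schwann and neural markers did not pass (7 of 13 higher, adjusted p = 0.558), with the receptor RET at 55.4 ± 36 and 167.9 ± 69 and NGFR at 20.3 ± 5.1 and 14.5 ± 11. Immune cell markers did not pass either (7 of 14 higher, adjusted p = 0.892), with LAPTM5 at 57.7 ± 7.8 and 35.1 ± 8.7 and CD68 at 72.4 ± 36 and 36.3 ± 13.

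**Figure D4:**
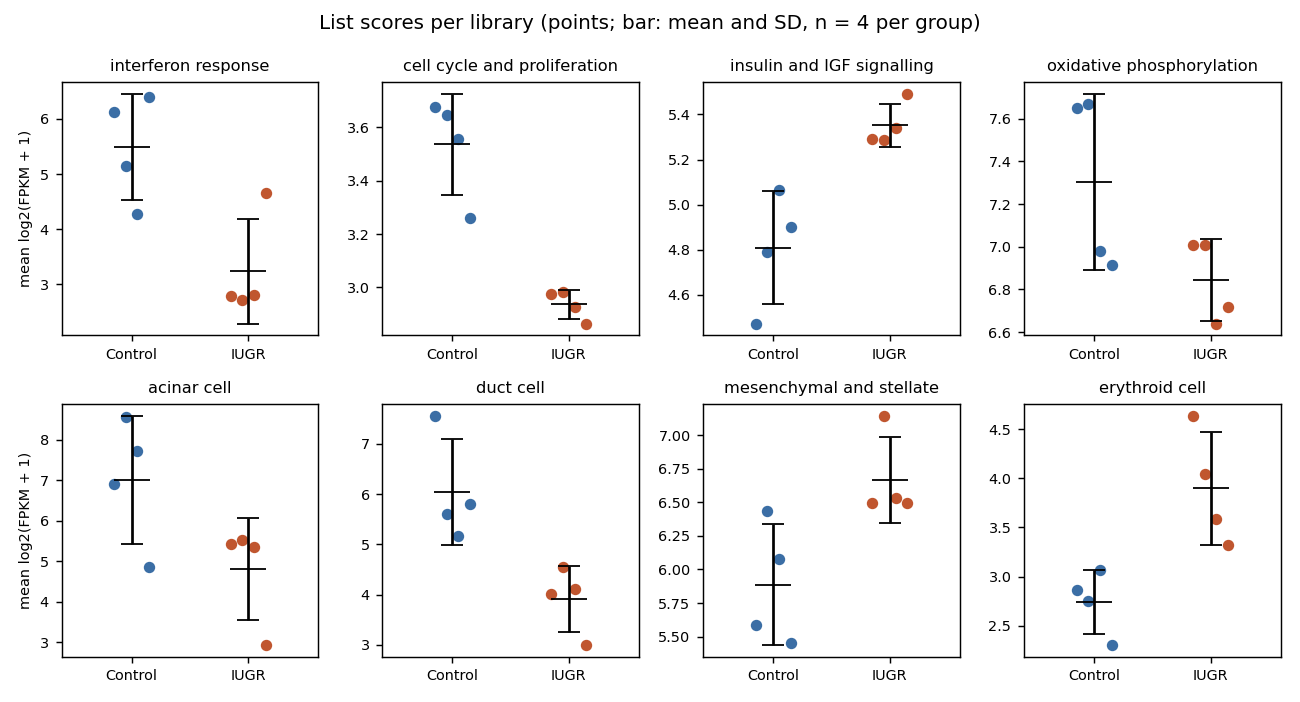
Mean log2(FPKM + 1) of 8 gene lists (vertical axes, which do not start at 0) in the 4 control (blue) and 4 IUGR (orange) libraries, with group means and SD as bars. The cell cycle scores are 2.86 to 2.98 in IUGR and 3.26 to 3.68 in controls, and the duct scores 2.99 to 4.55 and 5.18 to 7.57.

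As scores per fetus, duct markers were 6.04 ± 1.1 in controls and 3.91 ± 0.66 in IUGR, mesenchymal markers 5.89 ± 0.45 and 6.67 ± 0.32, and erythroid markers 2.74 ± 0.33 and 3.90 ± 0.58 (SD, n = 4). Each of the 3 separated the groups without overlap, with an exact permutation p of 0.0286, or 0.0857 adjusted over the 9 marker lists. Acinar scores were 7.01 ± 1.6 and 4.81 ± 1.3 (exact permutation p = 0.114). None of the 9 scores passed after adjustment, and the smallest p the design allows limits this test.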

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

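The tests of immune cells, of the endocrine share and of scaling, and the fit with the duct score, were chosen only after related results had been seen. Within-group values were compared by the gap between an extreme library and its neighbour, on log2(FPKM + 1) for genes, and a gap above 0.829 of the range of 4 libraries was marked. Of 214 groups of values 10 were marked, or 4.67%, about the 1 in 20 that chance gives. Among all tested genes the share was 4.07% in controls and 6.87% in IUGR.

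IUGR 4 stood apart from the other IUGR libraries in the interferon score (4.66, against 2.70 to 2.80) and the acinar score (2.92, against 5.36 to 5.53). IUGR 2 stood apart in WFDC10A (541.8 FPKM, against 47.3 to 66.0), NGFR (31.3, against 8.02 to 9.60), the endothelial score (5.51, against 5.26 to 5.29) and the mesenchymal score (7.15, against 6.50 to 6.53). UCP2 was 26.7 FPKM in IUGR 1 against 66.3 to 74.7 in the other 3, and TEK was 36.3 in IUGR 4 against 25.3 to 26.8. Among controls, HSPA1L was 9.33 FPKM in Control 2 against 1.92 to 2.23, and COL5A1 was 21.4 in Control 1 against 31.6 to 32.7.

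Interferon response genes were lower in IUGR by 2.25 in mean log2, and 2 of 35 splits of the libraries gave a mean change as large. With the acinar score in the fit the difference was -3.50 ± 0.53 (SE), which argues against acinar RNA in the controls. With sex in the fit it was -2.61 ± 0.80, against the uneven sexes. The immune cell markers had a median log2 fold change of 0.038 ± 0.24, against -1.90 for the interferon list. That argues against a general excess of immune cells in the controls, but not against more of a single immune cell type. Of the 14 markers 7 were higher and 7 lower in IUGR, with CD68 and LAPTM5 among the lower. With the duct score in the fit the mean of the immune list was -1.01. Duct RNA cannot be told apart from growth restriction, since the duct score separates the groups and its fit left -2.17 with an SE of 1.28. Growth restriction itself, the heat that produced it and an antiviral response in some control fetuses all stay open as hypotheses and were not tested.

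Cell cycle genes were lower in IUGR by 0.598 in mean log2 (SE 0.099). The difference was -0.43 ± 0.088 with the acinar score in the fit, -0.65 ± 0.12 with sex and -0.64 ± 0.084 with gestational age, so none of these accounts for it. Slower division of islet cells in growth restriction and a change in which cell types were picked both stay open and were not tested, and counting dividing cells by cell type would tell them apart.

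Acinar markers were lower in IUGR by 2.20 ± 1.0 (SE) in mean log2, and 4 of 35 splits gave a mean change as large. A larger share of endocrine cells in IUGR islets alone would lower every other cell type alike, but mesenchymal markers moved 2.98 above acinar markers, more than their summed SE of 1.29. A scaling factor per library moves all genes alike, so scaling alone would not give this gap. Both directions had been seen before the gap was taken, so it is no separate support for the acinar difference. A part played by the endocrine share or by scaling was not excluded. Less exocrine tissue carried along with IUGR islets at hand-picking and a true difference in the pancreas both stay open and were not tested.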

How the results depend on the processing

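The fits without Control 1 and Control 4, with the duct score, and with rows of very high FPKM left out of the hormone denominator were chosen after seeing the data. With the preset correlation, the interferon list (mean log2 fold change of -3.50 to -1.10) and the cell cycle list (-0.74 to -0.41) kept their direction and call in all 24 refits. Over all lists and refits, 585 results kept their direction and their side of the threshold, 88 lost the call and 4 gained it. Another 40 changed direction relative to the other genes. The 585 include refits of lists that had no call to keep. The call of cell cycle inhibitors and apoptosis was lost in 14 of 24 refits and that of smooth muscle in 11. Depth is unknown, so its effect on low genes was not measured. The cause of the changes below was not tested, except that fewer libraries remain when some are left out. Rescaling to the same sum is a further exception, since a few rows inflate that sum. In Control 3, IUGR 3 and IUGR 4, 1 row held 27.7%, 24.6% and 33.6% of all FPKM, while the library medians lay close together. That scaling therefore lowers all other genes in these libraries. Fits with a marker score gave no value for that marker's own list. The duct and mesenchymal scores separated the groups without overlap, so fits with either cannot tell the score apart from growth restriction.

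Against 3 genes changed, the count was 1 with a pseudocount of 0.1, 0 without a filter, 100 with libraries rescaled to the same sum, 5 without the 20 highest genes, 0 with quality weights, 0 with gestational age, 116 with the acinar score, 0 with the mesenchymal score, 0 without Control 1 and Control 4, 0 with the duct score, and 0 to 12 on leaving out 1 library. Leaving out the 20 highest genes moved the median of all genes by 0.213 and the split at p under 0.05 to 1893 higher and 530 lower, against 1054 and 1261. The mesenchymal score moved it by -0.101. Against 21 lists, 7 passed with the mesenchymal score, 12 without both controls, 12 with the duct score, 0 with an estimated correlation, 1 by fry in one direction and 8 in either.

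The replicate block gave 11 genes (4 higher, 7 lower) and 20 lists. Libraries of the same number deviated together with correlations of -0.038, 0.251, 0.101 and 0.228. Control 2, Control 3 and Control 4 each correlated best with the IUGR library of their own number. For Control 3 the margin was narrow (0.1015, against 0.1010 with IUGR 1), and Control 1 correlated best with IUGR 2 (0.106). The numbers were not taken as pairs in the main test, but a pairing was not excluded. With the block 2907 genes had an unadjusted p under 0.05 (limma), against 2315 without it.

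Directions changed as follows, in mean log2 for lists and log2 for genes, where the direction of a list is relative to the other genes and can turn while its mean stays above 0. For immune markers it was 0.035 with no filter, -0.014 at a mean of 5, 0.28 without the 20 highest genes, 0.079 by quantiles, 0.021 with quality weights, 0.12 with the replicate block and 0.058 with the acinar score. PDX1 was 0.23 without the 20 highest, 0.0068 by median-of-ratios, 0.31 by quantiles and 0.29 with the acinar score. Non-beta markers were 0.37 without the 20 highest and -0.16 with the acinar score, where glycolysis was -0.089.

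With the mesenchymal score the values were -0.33 for transcription factors, 0.47 for cytokines, 0.085 for lipid synthesis, 0.20 for genes kept low, -0.19 for endothelial, -0.27 for smooth muscle, -0.20 for Schwann and -0.30 for immune markers, -0.024 for GCK, -1.04 for MAFA, -0.26 for FOSB and 0.028 for CD68. Without both controls they were -0.17 for transcription factors, 0.044 for cytokines, 0.084 for genes kept low, -0.35 for immune markers, -0.23 for GCK and -0.72 for MAFA.

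With the duct score they were -0.055 for transcription factors, -0.17 for glucose sensing, -0.23 for granules, 0.084 for apoptosis, 0.23 for heat shock, 0.068 for lipid synthesis, 0.062 for genes kept low, -0.24 for endothelial, -1.01 for immune and -0.20 for non-beta markers. Of these lists only granules and immune markers passed in the new direction (camera, adjusted p = 0.0289 and 5.14e-07). Among genes they were 0.042 for PDX1, 0.060 for UCP2, -0.045 for ADRA2A, -1.002 for GCK and -0.10 for MYT1. They were -0.26 for SYT7, 0.013 for PFKP, 0.86 for CRYAB and -0.26 for TEK. CLDN4 was at 0.64, but it belongs to the duct score itself, so its change of direction carries no weight.

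On leaving out 1 library the ranges that crossed 0 or changed direction were -0.20 to 0.32 for immune markers as list and score, -0.020 to 0.26 for non-beta markers as list and score, -0.011 to 0.14 for glycolysis, 0.24 to 0.69 for hormones, -0.18 to 0.19 for PDX1, -0.043 to 0.57 for GCK and -0.071 to 1.12 for MAFA. The hormone share stayed lower in IUGR in all 10 alternatives. On leaving out 1 library its difference, -0.0617 percentage points with all 8, ran from -0.102 without Control 3 to -0.0341 without Control 2.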

Other observations

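The 4 lists described here, and the tests of clock, imprinted and basement membrane genes as groups, were chosen after related results had been seen, and their counts over other splits were added after the group tests. Basement membrane genes, the laminins, type IV collagens and nidogens that surround islets and vessels, were higher in IUGR for 16 of 18 tested members, with a median log2 fold change of 0.62 (camera, adjusted p = 0.000136, and 0.303 with an estimated correlation). The laminin chain LAMA2 rose from 1.88 ± 1.7 to 9.68 ± 1.0 FPKM (SD, n = 4) in adjustment over the list alone. Nidogen NID1 was at 36.2 ± 14 and 66.4 ± 5.7 FPKM in control and IUGR, and the heparan sulfate proteoglycan HSPG2 at 22.1 ± 14 and 42.3 ± 1.9. Mesenchymal markers, with a median of 0.77, were higher alongside them, and Control 1 and Control 4, which stood apart, held the lowest values of all 3 (LAMA2 0.554 and 0.442, HSPG2 10.4 and 13.3, NID1 18.8 and 32.5 FPKM). Imprinted genes, expressed from 1 parental copy, were higher for 12 of 14 members (median 0.62, adjusted p = 0.00171, and 0.303 with an estimated correlation). IGF2, IGF2R and PEG3 rose in adjustment over the list alone, PEG3 from 131.0 ± 139 to 416.0 ± 124 FPKM, and the first 2 also belong to the insulin and growth factor list. Control 1 was the lowest library for all 3 genes (PEG3 27.6 FPKM, against 335.4 in Control 3).

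Circadian clock genes were higher for 10 of 14 members (adjusted p = 0.0352, and 0.303 with an estimated correlation), and the clock activator ARNTL rose from 13.6 ± 3.1 to 34.5 ± 8.0 FPKM in adjustment over the list alone. Cytosolic ribosomal protein genes were lower for 24 of 25 members, by a median log2 of -0.27, with no member past the threshold (adjusted p = 0.0352, and 0.610 with an estimated correlation). Chance was not excluded for any of the 4 lists. A mean change as large appeared in 2 of 35 splits for basement membrane genes (0.618 against 0.653 in the highest other split), 4 for imprinted genes (0.589 against 0.725), 6 for clock genes (0.331 against 0.442) and 18 for ribosomal protein genes (0.237 against 0.550).

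The 3 genes past the threshold exceeded every other split of the 8 libraries into 4 and 4, since 1 of 35 splits, the real one, gave as many and the highest other gave 2. That margin is too small to carry weight, since WFDC10A, 1 of the 3, was listed at 0 in all controls in a locus of 144 bp. The real split was also the largest for 2315 genes at an unadjusted p under 0.05 (1 of 35, highest other 2207) and for 21 lists (1 of 35, highest other 19). Other splits still passed 5 to 19 lists, with a median of 10, and some of these splits keep 3 of the 4 controls on one side and so carry part of the real difference. The cell cycle mean change of 0.598 in size was exceeded by no other split (1 of 35, highest other 0.459). For the interferon list 2 of 35 splits gave a mean change as large, 2.25 in the real split and 2.44 when Control 3 and IUGR 4 changed places, so chance was not excluded. The size was largest in the real split also for the tricarboxylic acid cycle (0.451 against 0.405 in the highest other), insulin and growth factor (0.543 against 0.434), duct (2.125 against 1.81), mesenchymal (0.780 against 0.750) and erythroid lists (1.15 against 1.03). These counts were not adjusted over the 30 lists. For duct, mesenchymal and erythroid markers they repeat the permutation test of the scores. For the stress response list the highest other split was about equal (0.52357 against 0.52347). The remaining lists past the camera threshold were matched by other splits. Of 35 splits, the real one included, 12 were as large for complement, 10 for glucose sensing, 9 for cytokines and 8 for immediate early genes. The count was 7 for endothelial markers, 6 for oxidative phosphorylation, 6 for apoptosis and 5 for hypoxia. For smooth muscle and acinar markers it was 4 each, for granules 3, and for adrenergic and antioxidant genes 2 each.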
